A study of Oryzias latipes with 22 samples.

How the data were processed

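RNA from whole medaka larvae was labelled with Cy3 and hybridised to single-colour Agilent arrays, 1 array per sample. The arrays were read with Agilent Feature Extraction, version 9.1 per the submitters' processing notes and 9.5.3.1 per the file headers. The deposited scanner files hold a processed intensity for each spot, which was background-subtracted and detrended within the array per the file headers and not normalized between arrays. The deposited series table holds the same intensity multiplied by 1 factor per array. The factor lay between 0.650 and 2.21, and each array's median was 391.8 over the values it kept. That table is on a linear scale and not centred per probe. It leaves 55388 values blank by a rule that is not stated.

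Groups were taken from the sample titles. Control spots (1417 per array) were left out, and spots flagged as non-uniform, at most 37 per array, were set to missing. The log2 of the processed intensity was reduced by each array's 75th percentile over the 36398 probes. The 31512 probes that the scanner software called well above background on all arrays of at least 1 group were tested. The log2 values were fitted with limma 3.58.1 in R 4.3.3 on all 22 arrays, with 15 residual degrees of freedom for the groups and 20 for the slope over dose rank (0 to 6). Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Each probe had 1 spot per array, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.

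The fits were tested on simulated data for 31512 probes with the measured means and spreads. Of 200 probes changed at 60 ng/L, 0% were recovered at a log2 change of 0.5, 66.0% at 1 and 93.0% at 2. For the trend the shares were 19.5%, 75.0% and 97.0% for a total change of these sizes. Errors were drawn independently, without shared scan day effects, and only 200 of the 31512 probes changed. The shares therefore do not describe recovery where many probes change or where scan day acts. A second simulation gave the arrays scan day effects of the measured size and no dose effect. Without a block it called 6896 probes at 6 ng/L and 6850 at 200 ng/L, and with scan day as a block 0 at each. The effects came from the blocked fit of these data and were added in the form that fit assumes. The 0 therefore follows from the setting and is no test of the block. The added effects also held the estimation error of that fit, so 6896 and 6850 do not measure how many calls scan day caused.

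The tests, the groups and most alternatives were fixed before the data were examined. The alternatives were quantile normalization, normexp background correction with an offset of 50, the series table, other filters on dim probes, 2-group fits, blocks for replicate number, slide and scan day, array weights, another variance prior, other thresholds, other dose scores and each array left out in turn. Scan day as a fixed block, the comparisons within scan days, a step at 20 ng/L and fits without replicate 3 of 20 or 60 ng/L were chosen after the data were seen. So were keeping the non-uniform spots and scan day as a random block for the slopes of single probes. Together these gave 48 values for 19 results, besides single arrays left out. Of those results, 7 were comparisons that had not been planned. The blocked and within-day changes of the 4 named probes, with and without replicate 3 of 20 ng/L in the blocked fit, were added too.

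No probe ID matched the 26845 genes of the gene table (assembly ASM223467v1), so the planned tests of gene lists and the planned rule for named genes could not be applied. In their place, the probes named are the steepest rises and falls among those well above background on all 22 arrays that the trend called both with and without scan day as a block, ranked by the blocked slope. The replicate numbers of the labels did not pair the samples throughout. Over 63 pairs of same-numbered arrays of different doses, the median correlation of deviations from the group means was 0.00062. The correlations ran from -0.346 to 0.478, and 18 were over 0.1. Some same-numbered arrays shared a slide, such as replicate 1 of 0, 2 and 20 ng/L. No 2 arrays of a group held the same values, the smallest SD of a log2 difference between 2 of them being 0.212.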

Results

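Gene expression was measured in whole larvae of the Japanese medaka, Oryzias latipes, a small freshwater fish, after 7 days in water containing 17β-trenbolone. This synthetic steroid binds the androgen receptor and is used to promote growth in cattle. The series compared a control (0 ng/L) with 6 concentrations, of which the low ones were 2 and 6 ng/L, the middle ones 20 and 60 ng/L and the high ones 100 and 200 ng/L. The series title names the regulation of cholesterol synthesis genes as its subject. There were 4 control samples and 3 samples at each other dose, and each sample was a pool of 30 larvae from a chamber of 90. Each of the 22 samples was hybridised to 1 single-colour array with 36398 probes. The labels say that the samples of a dose came from its chamber, so p-values measured the spread between pools and not between chambers. Arrays of 0, 2, 20, 60 and 100 ng/L were scanned on more than 1 day each. Without a block, that spread entered the p-values too. The 4 control pools hold more larvae than 1 such chamber, and the labels do not say where the fourth came from. The files pair no probe with a gene name, and 0 of the 36398 probe IDs were found in the gene table of the medaka genome. Changes are therefore given as numbers of probes, with 4 probes described by their sequence, and the cholesterol synthesis genes could not be picked out.

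The probes well above background numbered 27351 to 32578 per array. The 75th percentile of the processed intensity ran from 822 to 2309. The arrays were scanned on 5 days, numbered here in order, and the doses were spread unevenly over them. Scan day 1 held 10 arrays, namely all arrays of 6 and 200 ng/L, replicates 2 and 3 of 2 ng/L, and replicate 3 of both 20 and 60 ng/L. All 4 controls were scanned on days 2 and 3, with the remaining arrays of 2, 20 and 60 ng/L, and the 100 ng/L arrays alone on days 4 and 5. The median local background was 311 to 316.5 on scan day 1 and 36 to 41 on the other days. The first principal component held 38.9% of the variance and separated the arrays of scan day 1 from the rest. Scan day alone accounted for 58.3% of the variance and dose alone for 49.7%. After scan day, dose accounted for a further 18.5%, and after dose, scan day for a further 27.1%. The 100 ng/L arrays had days 4 and 5 to themselves, so their difference could not enter the 18.5%. These shares were not corrected for the unlike numbers of doses and days, so they do not rank the effects of dose and scan day.

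**Figure D1:**
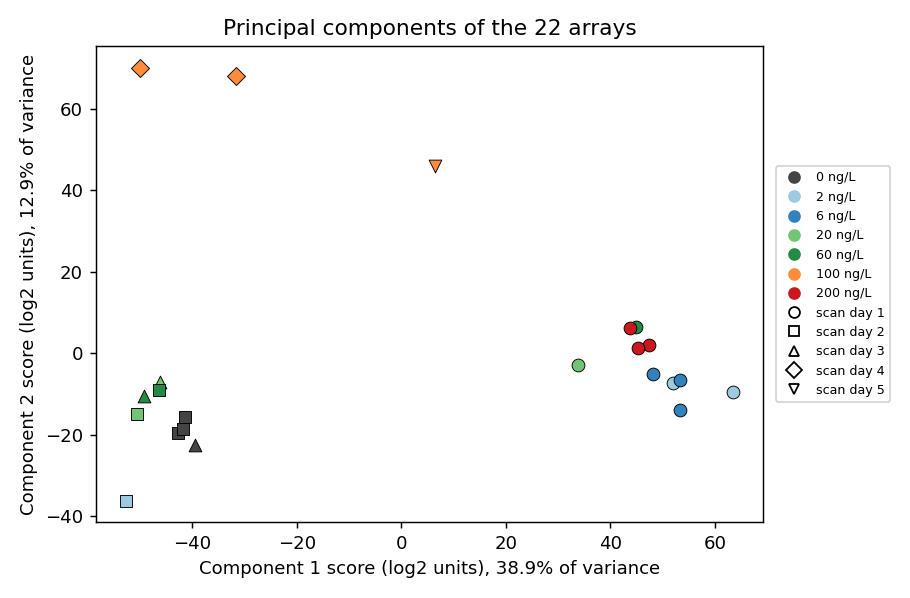
Scores of the 22 arrays on the first 2 principal components, in log2 units, coloured by dose and shaped by scan day. The 10 arrays of scan day 1 lie at scores of 33.88 to 63.39 on component 1, and the 100 ng/L arrays lie apart on component 2.

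Arrays of 1 dose scanned on different days had a median correlation of 0.978 over probes, and arrays of different doses scanned on the same day one of 0.992. Values with scan day as a block are therefore given beside the comparisons where such a fit could be made. That fit used 19 arrays, since the 100 ng/L arrays had scan days of their own.

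At 2 ng/L, 118 probes rose and 18 fell against the control among the 31512 tested (limma, Benjamini-Hochberg adjusted p under 0.05). With scan day as a block, 17 rose and 7 fell, and 16 of the 136 probes were called in the same direction by both fits. Within scan days 2 and 3, where 1 array of 2 ng/L met the 4 controls, limma called 0 probes, with 3652 at an unadjusted p under 0.05, but a single exposed array says little about this dose. The count of 136 depended on which arrays entered: it was 8046 without replicate 1, 3 without replicate 2 and 8 without replicate 3, and 46 to 76 without 1 control.

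At 6 ng/L, 3335 probes rose and 2505 fell, with median log2 changes of 0.76 and -0.58. Leaving out any 1 of the 7 arrays gave 761 to 3653 probes. Each 6 ng/L array was scanned on day 1 and each control on day 2 or 3. The fit with scan day as a block called 182 rises and 51 falls, and 172 of the 5840 probes were called in the same direction by both fits. Another 556 of them had the opposite sign in the blocked fit. The blocked fit reached the controls only through 2, 20 and 60 ng/L, the doses scanned both on day 1 and on the control days. On day 1, replicate 3 of both 20 and 60 ng/L stood apart from the 2 and 6 ng/L arrays. The blocked counts at this dose therefore also depend on arrays of other doses. Within scan day 1, limma called 0 probes between 6 and 2 ng/L, with 2170 at an unadjusted p under 0.05 in a fit of those arrays alone (3 against 2) and 2836 with the 200 ng/L arrays of that day in the fit.

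At 20 ng/L, limma called 0 probes against the control, with 2615 of 31512 at an unadjusted p under 0.05. The blocked fit called 1 rise and 6 falls. The array of replicate 3 differed from the other 2, and 36 probes were called without it. Leaving out replicate 1 or control replicate 4 gave 1 probe. Within scan days 2 and 3, which hold replicates 1 and 2 and the controls, 72 probes rose and 97 fell with scan day as a block. Without that block 180 rose and 274 fell. Array weights, which gave replicate 3 a weight of 0.101, called 1753 probes.

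At 60 ng/L, 128 probes rose and 216 fell, with median log2 changes of 0.85 and -0.84. With scan day as a block the count was larger: 349 rose and 1098 fell, and 337 of the 344 probes were called in the same direction by both fits. Within scan days 2 and 3, 388 rose and 738 fell with 2 arrays of 60 ng/L. With slide as a fixed block, on 16 arrays with 4 residual degrees of freedom, 0 were called. The count was 91 without replicate 3, 227 without replicate 2, 634 without replicate 1 and 92 to 206 without 1 control. Replicate 3 stood apart from its scan day, with correlations of 0.981 to 0.983 with the 2 and 6 ng/L arrays of that day, against 0.994 to 0.997 among those. On the series' own scaled values, 39 probes rose and 16 fell, so that the share of rises went from 37.2% to 70.9%.

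At 100 ng/L, 2148 probes rose and 3893 fell, with median log2 changes of 0.55 and -0.63. Without replicate 1 the count was 3339. No other dose was scanned on days 4 and 5, so the dose and these scan days cannot be told apart. With scan day as a random block, 161 probes rose and 602 fell. On the series' own scaled values the share of rises was 63.6%, against 35.6% here.

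At 200 ng/L, 3212 probes rose and 2718 fell, with median log2 changes of 0.69 and -0.60. As at 6 ng/L, no array shared a scan day with a control, and leaving out any 1 of the 7 arrays gave 491 to 3185 probes. Blocking on scan day gave 248 rises and 529 falls, and 154 of the 5930 probes were called in the same direction by both fits, while 415 had the opposite sign in the blocked fit. Here too the blocked fit reached the controls only through the arrays of 2, 20 and 60 ng/L, and its counts depend on them. Scan day as a random block called 37 rises and 29 falls, and slide as a random block 3 probes in all. On the series' own scaled values the shares of rises were 86.8% at 200 ng/L and 86.9% at 6 ng/L, against 54.2% and 57.1% here.

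**Figure D2:**
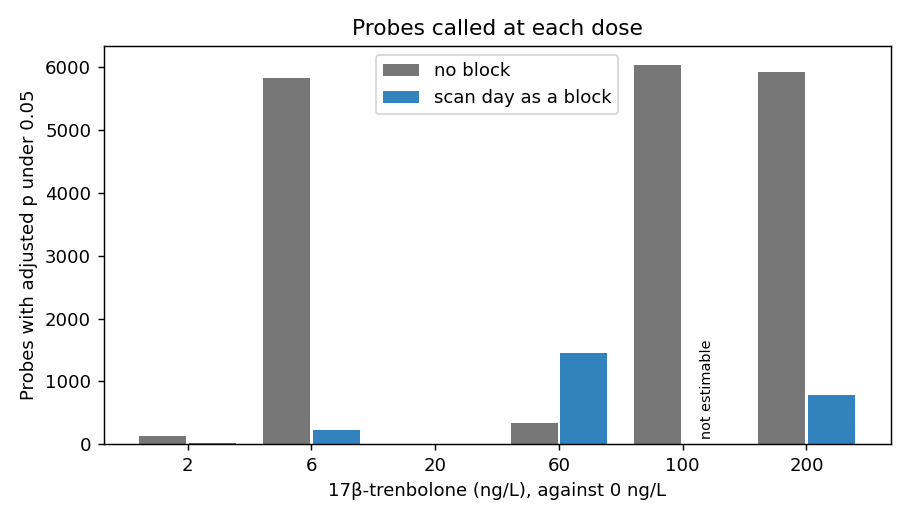
Number of probes with an adjusted p under 0.05 against the control at each dose, without a block (grey) and with scan day as a block (blue). The counts of 5840 at 6 ng/L and 5930 at 200 ng/L became 233 and 777 with the block, and that at 60 ng/L went from 344 to 1447. At 6 and 200 ng/L the blocked fit reached the controls only through the arrays of 2, 20 and 60 ng/L.

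The 200 ng/L arrays could be set against the 2 and 6 ng/L arrays of the same scan day, a comparison chosen after the data were seen. Against the mean of those doses, 1771 probes were higher and 2341 lower at 200 ng/L (3 arrays against 5). The count of 4112 was 1776 to 2146 without 1 of the 200 ng/L arrays and 2470 without replicate 2 of 6 ng/L. Against 2 ng/L alone it was 840, and against 6 ng/L alone 3728. The median log2 differences were 0.31 and -0.42, and 47 probes were higher and 189 lower by at least 1 on the log2 scale. The 200 ng/L arrays shared 1 slide that held no other dose. With slide as a random block 2588 probes were called.

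Over the rank of the dose, 454 probes rose and 412 fell across all 22 arrays. Under the scan day block, 31 rose and 33 fell. Both fits called 19 rises and 8 falls in common. The trend called 2 probes over the log2 dose among exposed arrays and 58 over the dose on a linear scale. It called 2200 without 200 ng/L. Without 100 and 200 ng/L it called 60, and with slide as a fixed block on those same 16 arrays it called 0. The 60 were 4 rises and 56 falls. On the series' own scaled values, 293 probes rose and 37 fell. The count ran from 198 without control replicate 4 to 1396 without replicate 3 of 20 ng/L, and leaving out 1 array moved it by over 1.5 times for 11 of the 22. Those were the 4 controls, replicate 1 of 2 ng/L, replicate 3 of 20 ng/L, the 3 arrays of 100 ng/L and replicates 1 and 3 of 200 ng/L.

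Of those 27 probes, the 2 with the steepest rise and the 2 with the steepest fall were chosen after their values were seen. Since they were chosen for passing both fits, that they pass them is no evidence of its own. The comparisons of single doses below use the same arrays, so their folds and p-values are also favoured by that choice. All 4 were well above background on every array. Probe TC51660 (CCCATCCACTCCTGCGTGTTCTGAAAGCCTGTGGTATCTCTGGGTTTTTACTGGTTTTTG) had a log2 intensity of 4.24 ± 0.06 (SD, n = 4) above the array's 75th percentile in the control. It stood at 3.97 ± 0.11 at 2 ng/L and 4.11 ± 0.12 at 6 ng/L (SD, n = 3). At 60, 100 and 200 ng/L it stood at 5.13 ± 0.39, 5.45 ± 0.16 and 5.16 ± 0.14. At 100 ng/L this was 2.31-fold the control (limma, adjusted p = 0.0157). At 200 ng/L the 1.90-fold difference had an adjusted p of 0.0544. Against the 2 and 6 ng/L arrays of its own scan day, 200 ng/L was 2.12-fold (limma, adjusted p = 0.000322), and with scan day as a block 3.30-fold the control (limma, adjusted p = 0.0284). That blocked value depended on replicate 3 of 20 ng/L and was 2.23-fold without it (limma, adjusted p = 0.0164). Probe TC59699 (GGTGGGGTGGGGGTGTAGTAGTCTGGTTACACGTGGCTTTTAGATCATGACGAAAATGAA) rose from 0.97 ± 0.23 in the control to 2.54 ± 0.08 at 100 ng/L and 2.54 ± 0.05 at 200 ng/L. These were 2.98-fold and 2.96-fold (limma, adjusted p = 0.00291 and 0.00942). At 2 ng/L the arrays of scan day 1 stood at 1.67 and 1.71 and that of scan day 2 at 0.79, and at 6 ng/L the mean was 1.51 ± 0.06. Against the 2 and 6 ng/L arrays of its own scan day, 200 ng/L was 1.92-fold (limma, adjusted p = 9.05e-05), and with scan day as a block 3.81-fold the control (limma, adjusted p = 0.0452). Without replicate 3 of 20 ng/L the blocked value was 2.37-fold (limma, adjusted p = 0.0461).

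Probe BJ025599 (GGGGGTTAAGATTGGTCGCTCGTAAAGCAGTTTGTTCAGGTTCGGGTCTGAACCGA) fell from 1.85 ± 0.07 in the control to 0.66 ± 0.33 at 60 ng/L and 0.38 ± 0.20 at 100 ng/L, and stood at 1.17 ± 0.21 at 200 ng/L. The ratios to the control were 0.440, 0.361 and 0.624 (limma, adjusted p = 0.00771, 0.000137 and 0.0268). The blocked ratios were 0.402 at 60 ng/L and 0.447 at 200 ng/L (limma, adjusted p = 0.000919 and 0.00817). Within scan day 1 the ratio of 200 ng/L to 2 and 6 ng/L was 0.784 and did not pass (limma, adjusted p = 0.174). Probe TC48364 (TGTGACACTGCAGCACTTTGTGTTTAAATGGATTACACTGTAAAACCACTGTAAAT) had values of 0.08 ± 0.32 in the control and -0.84 ± 0.11 at 200 ng/L, a ratio of 0.530 (limma, adjusted p = 0.0321). This was 0.316 with scan day as a block and 0.589 against 2 and 6 ng/L within scan day 1 (limma, adjusted p = 0.0109 and 0.00888). The blocked value was 0.411 without replicate 3 of 20 ng/L (limma, adjusted p = 0.0139). At 60 and 100 ng/L the ratios of TC48364 to the control were 0.537 and 0.613 and did not pass (limma, adjusted p = 0.125 and 0.0809). At 6 ng/L the ratio was 1.04. The blocked slopes of TC51660, TC59699, TC48364 and BJ025599 had adjusted p of 0.0123, 0.0429, 0.0341 and 0.0496 (limma). The trend of TC48364 passed the threshold narrowly (adjusted p = 0.0443) and missed it in 13 of the 22 fits that left out 1 array. At 20 ng/L, replicate 3 lay apart from replicates 1 and 2 for these probes. TC51660 stood at 5.54, 5.31 and 3.45 in replicates 1, 2 and 3, and BJ025599 at 0.84, 0.79 and 1.57, each below every control.

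**Figure D3:**
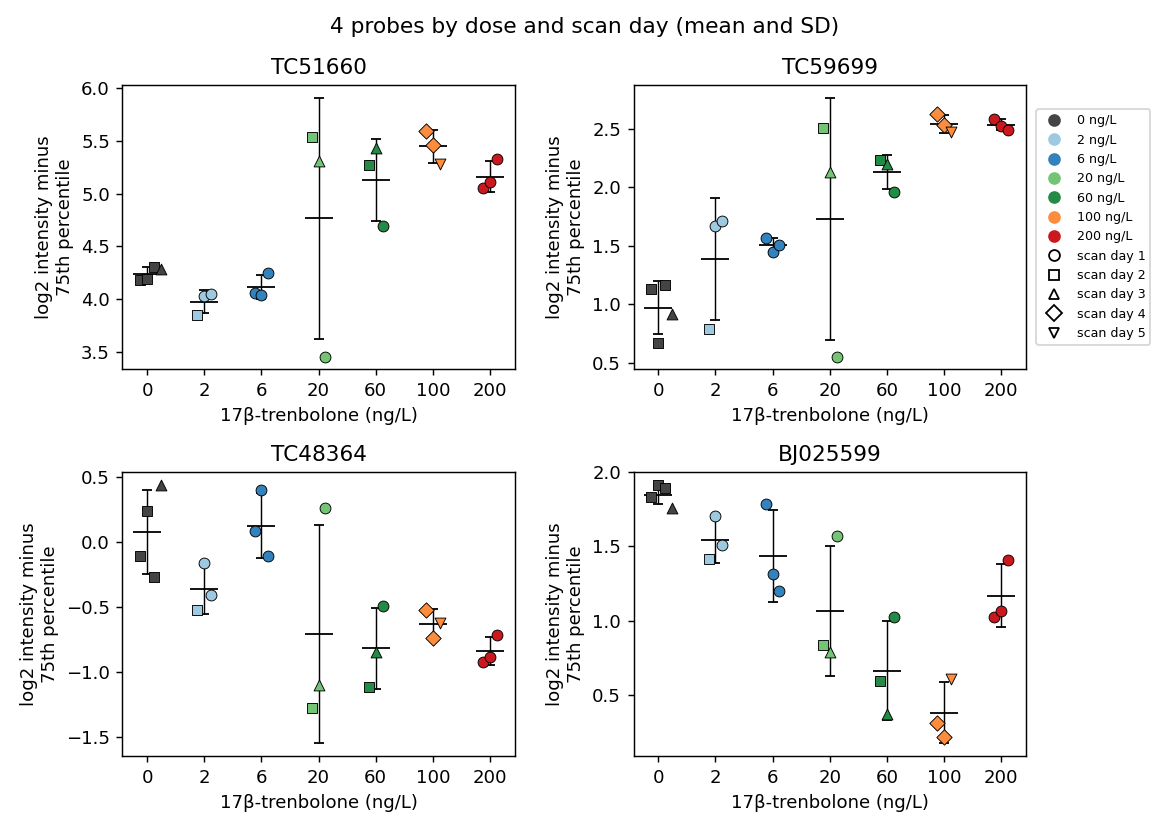
Log2 intensity of 4 probes relative to the array's 75th percentile at each dose of 17β-trenbolone in ng/L, with 1 point per array shaped by scan day, and the mean and SD per dose. TC51660 lies between 4.18 and 4.30 in the controls and between 5.05 and 5.60 at 100 and 200 ng/L, while replicate 3 of 20 ng/L lies at 3.45.

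The moderated F test over the 6 doses called 10110 probes as different among the 7 groups. Blocked on scan day, and without 100 ng/L, the number was 3386.

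Probes called in the same direction at a pair of doses were most numerous for 6 and 200 ng/L, at 3201, against 556 for independent lists and 0 in simulated unchanged groups sharing the controls. For 100 and 200 ng/L the number was 1453, against 555 and 0. The simulated groups held no change and no scan day effect, so an overlap of 0 follows from that setting and is no baseline. With the controls split into pairs, one for each dose, the mean numbers were 39.5 and 61.7. Fewer controls stood behind those calls, and no number for independent lists was computed for them. The correlation of log2 changes between 6 and 200 ng/L was 0.867 over probes, against 0.427 in the simulation, and the covariance 0.267 against 0.0286. Between 100 and 200 ng/L the correlation was 0.432 against 0.431, and the covariance 0.112 against 0.0289. The 6 and 200 ng/L arrays also shared their scan day. The 60 ng/L comparison within scan days 2 and 3 and the 200 ng/L comparison within scan day 1 shared no array. They had 67 rises in common against 21.8 for independent lists, and 38 falls against 54.8. A further 169 probes were higher at 60 ng/L and lower at 200 ng/L, against 28.8, and 25 the other way, against 41.5. The 20 ng/L comparison within scan days 2 and 3 shared 44 rises with that of 200 ng/L, against 4.05, and 11 falls, against 7.21. There, 14 probes were higher at 20 ng/L and lower at 200 ng/L, against 5.35, and 2 the other way, against 5.45. The 100 ng/L comparison with the control had 336 rises in common with that of 200 ng/L, against 120.7, and 374 falls, against 289. Of the 100 ng/L calls, 83 were higher at 100 and lower at 200 ng/L, against 159.6, and 83 the other way, against 219. The 100 ng/L changes also shared no array with that comparison, but their calls used a spread estimated from all 22 arrays.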

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

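The median local background of control replicate 4 was 41, far from the 36.5 to 37 of the other 3 controls relative to their range. It was the 1 control scanned on day 3. It was the 1 flag among 10 measures examined, and chance flags about 1 in 20.

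The tests below on scan day, background, slide and spike-in probes were stated before their values were seen. The test of a wrong label, and the use of the spike-in slope, were chosen after. The comparison of 200 ng/L within scan day 1 was also chosen after.

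More probes were called at 6 and 200 ng/L than at 2, 20 and 60 ng/L. The difference between scan days 1 and 2 within the 2 ng/L group rests on 1 array of day 2, replicate 1. That array had the lowest array weight of all, 0.097. The difference shares no array with the other comparisons. It correlated over probes with the changes at 6 ng/L at 0.843 and at 200 ng/L at 0.828, and 97.7% and 96.3% of the called probes had its sign. The differences between scan day 1 and the other days within 20 and 60 ng/L, each with 1 array on day 1, gave lower correlations of 0.518 and 0.569 at 6 ng/L and 0.424 and 0.571 at 200 ng/L, with 68.9% to 81.7% of called probes of the same sign. This is consistent with many of these calls following scan day, which may stand for anything that went with it, from labelling to the batch of fish. The higher background of that day was predicted to give more calls among dim probes if it were the cause. Of 3 equal classes of 10504 probes the dimmest had 14.1% called at 6 ng/L and the brightest 19.8%. Calls also depend on precision, which is limited for dim probes, so these shares do not decide whether background was the cause. An effect of 6 ng/L itself stays open, since no control was scanned that day.

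Within scan day 1, 4112 probes differed between 200 ng/L and the 2 and 6 ng/L arrays. In a plain 2-group fit the real split called 4165. It was the 1 split of 56 to reach that number, and the highest other called 19. With 56 splits of a comparison chosen after the data were seen, this speaks against chance between pools but does not exclude it. Between slide 3 and slides 1 and 2, among the 2 and 6 ng/L arrays, 0 probes were called (limma, 1938 at an unadjusted p under 0.05). The slide of the 200 ng/L arrays held no other dose, so slide and dose cannot be told apart here, and the dose stays open.

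Replicate 3 of 20 ng/L stood apart from its scan day. Its highest correlation with a 2 or 6 ng/L array of that day was 0.986, below the 0.994 to 0.997 among those arrays. The array was picked because it stood apart, so a low correlation was favoured by that choice. The value therefore does not decide whether it is a mislabelled array of those doses. Its spike-in probes deviated by 0.105 on the log2 scale on average, within the 0.0242 to 0.447 of the other arrays of the day. Its spike-in slope of 0.932 was the lowest of that day, so array quality stays open, as do a difference between pools of larvae and a wrong label.

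Other splits of the 7 arrays of each comparison, 35 per dose, were counted. At 6, 60, 100 and 200 ng/L, 1 split, the real one, reached the real count of 5840, 344, 6041 and 5930, and the highest other called 1, 1, 3 and 1. This speaks against chance among the pools there, but 35 splits are too few to exclude it. Pools of a dose came from its chamber, so the splits do not address differences between chambers. Scan day cannot be excluded either, since the real split at 6, 100 and 200 ng/L is also a split by scan day. At 2 ng/L, 2 splits reached 136, and the highest other called 1201 by putting control replicate 1 with the 2 arrays of scan day 1. That split points to the structure of the scan days, and the blocked count is 24. At 20 ng/L the real count was 0, so all 35 splits reached it. Over 100 regroupings of the 22 arrays, 3 reached the 866 trend probes, the highest other calling 5432, which also points to a structure of the arrays, and the blocked count is 64. For the F test 1 of 100 reached 10110, the highest other calling 103.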

How the results depend on the processing

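Scan day as a fixed block, the comparisons within scan days, the comparison of 200 with 2 and 6 ng/L with its alternatives, keeping the non-uniform spots, and scan day as a block for the slopes of single probes were chosen after the data were seen, and the other alternatives before. Unless stated, counts are given for the 6 doses from low to high and then the trend, and the cause was not tested. The main counts were 136, 5840, 0, 344, 6041, 5930 and 866. Quantile normalization, normexp and keeping non-uniform spots left these counts within 1.5 times. The series table gave 54, 1955, 0, 55, 2370, 2471 and 330, on the 30015 probes with a value on all 22 arrays. The median change over the probes fitted moved by up to 0.11 (log2), at 100 ng/L. Without a filter on dim probes the trend gave 568, and with probes well above background on all 22 arrays 20 ng/L gave 2. Fits of only the dose and the controls gave 0 at 2 ng/L, 16601 at 6 ng/L and 16993 at 200 ng/L, where the spread of the other doses no longer entered. With the replicate number as a block the counts were 84 at 2 ng/L, 177 at 60 ng/L and 106 for the trend, and the other counts stayed within 1.5 times; 10 of 21 arrays correlated best with an array of their own number. Slide as a random block gave 155, 624, 5, 520, 2877, 3 and 262, and 3321 for the F test. Scan day as a random block gave 99, 268, 4, 1137, 763, 66 and 330. Slide as a fixed block, on 16 arrays with 4 residual degrees of freedom for the groups and 7 for the trend, gave 0, 0, 1 and 0 at 2 to 60 ng/L and 0 for the trend. Array weights gave 15633, 19001, 1753, 2662, 13557, 19743 and 17474. In the group fit the lowest weights were 0.097 for replicate 1 of 2 ng/L and 0.101, 0.102 and 0.171 for replicate 3 of 20, 60 and 100 ng/L. Each of these was scanned on a day that no other array of its dose had. The same held for replicates 1 and 2 of 20 and 60 ng/L and control replicate 4, with weights of 0.99 to 1.79. With the low-weight arrays nearly left out, dose and scan day were harder to tell apart. The weighted counts are therefore no better measure of the dose. A robust prior with an intensity trend gave 1 at 20 ng/L. Requiring a log2 change of at least 1 as well gave 69, 1256, 0, 124, 830 and 1111, and adjusted p under 0.01 gave 38, 795, 0, 65, 2507, 392 and 20. The trend gave 2 over log2 dose among exposed arrays, 58 over linear dose, 2200 without 200 ng/L and 60 without 100 and 200 ng/L. Scan day as a fixed block gave 24, 233, 7, 1447 and 777 at 2, 6, 20, 60 and 200 ng/L, 64 for the trend and 3386 for the F test, and for the trend 446 without replicate 3 of 20 ng/L and 1615 without replicate 3 of 60 ng/L too. Within scan days 2 and 3 the counts at 2, 20 and 60 ng/L were 0, 169 and 1126 with scan day as a block, and 0, 454 and 1426 without it. Within scan day 2 alone, with 1 exposed array per dose, limma called 0 at each. Leaving out 1 array gave 3 to 8046 at 2 ng/L, 761 to 3653 at 6, 0 to 36 at 20, 91 to 634 at 60, 3339 to 6598 at 100, 491 to 3185 at 200 and 198 to 1396 for the trend. The 200 ng/L comparison within scan day 1 gave 4112, with 1776 to 4758 when 1 array was left out, 1355 at adjusted p under 0.01, 236 with a log2 difference of at least 1 and 2588 with slide as a random block. Overlaps summed over the 15 pairs of doses were 6289, with 190.7 when the controls were split and 400 at adjusted p under 0.01. The slopes of TC51660 and TC59699 passed the threshold in each of 7 alternatives and in each fit without 1 array; 1 of the 7, scan day as a fixed block, is a fit the probes were chosen for passing. That of BJ025599 missed it with the replicate block, and that of TC48364 in 3 of the 7; all kept their direction. Tests of gene lists and other probes of a gene were not run because no probe had a gene name. Slide as a fixed block could not be fitted at 100 and 200 ng/L, nor scan day at 100 ng/L. Dim probes limit the precision: as few as 27351 of the 36398 probes on an array were well above background.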

Other observations

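The tests in this part were chosen after the data were seen. A step between the doses below 20 ng/L and those from 20 ng/L on was fitted with scan day as a block and without 100 ng/L. It called 60 probes with all arrays and 1511 without replicate 3 of 20 ng/L. The trend with the same block went from 64 to 446 without that array, and to 1615 when replicate 3 of 60 ng/L was left out too. Both arrays were singled out from these data, so the larger counts are a hypothesis and not a measure of the dose effect. A response that sets in at about 20 ng/L may underlie them, and so may whatever set those arrays apart.

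Single arrays of scan day 1 were also set against the 3 arrays of 6 ng/L. Replicate 3 of 60 ng/L gave 11931 called probes and replicate 3 of 20 ng/L gave 5941, but both were picked because they stood apart in these data, so the counts show nothing further. The spike-in probes of replicate 3 of 60 ng/L deviated by 0.447 on the log2 scale, and those of replicate 3 of 2 ng/L by 0.313, on average. These arrays shared a slide.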
